A study of Mus musculus with 6 samples.

How the data were processed

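Expression was measured in 6 mouse samples of the C57BL/6 strain on 1-colour Affymetrix arrays, 3 of plasma cells from bone marrow and 3 of B cells from spleen. Per the labels' protocols, total RNA was extracted with a column kit for small samples, amplified with the NuGEN Ovation V2 system and labelled with biotin. Per the series design text, the plasma cells were taken 7 days after a boost with keyhole limpet hemocyanin (KLH, a protein antigen), enriched with magnetic beads against CD138 and then sorted, and each array used 50000 to 70000 plasma cells or 2000000 to 3000000 naive B cells. The amount of input therefore differed between the groups in the same way as the cell type.

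The deposited file holds intensity values on a linear scale, 1 value per probe set and array. How the authors summarised the probes, corrected the background and normalized the arrays is not given in the sources used here. In the deposited intensity values the upper quartile ranged only from 625 to 684 over the 6 arrays, and between 386 and 684 probe sets per array had a value of exactly 1. Every sample column of the file was matched to a sample through its name, and 0 columns were left unmatched.

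Of 45101 probe sets, 64 were control probe sets. The platform annotation, dated 2016, gave 1 gene symbol for 34945 of the others, several for 932 and none here for 9160. Symbols were updated through Entrez gene identifiers against the RefSeq gene table of assembly GRCm38.p6, in which 34741 of the 34945 matched, and the remaining probe sets kept the symbol of the platform annotation. No coordinates of that assembly were used. Probe sets with several symbols or none were kept out of the gene table and counted separately.

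Values were transformed as log2(intensity + 16), so fold changes are on that scale and understate the change of dim genes. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18193 genes, of which 9010 had several probe sets. Plasma cells were compared with B cells using limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p = 0.05. A 2-fold change means a log2 fold change of at least 1 in either direction. SE denotes the standard error of the fitted log2 fold change and SD the standard deviation over 3 arrays. Nothing in the labels says whether the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

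The level of signal expected without a target was taken from 27 control probe sets for bacterial genes other than the hybridisation spikes, whose 95th percentile lay between 23.0 and 41.8 on the 6 arrays. A gene at or below that percentile on all 3 arrays of a group has only an upper bound there, and its fold is given as "at least". That bound is computed from means of log2 intensities without the added constant, with the dim group set to the percentile of each array where it lay below it. On all 6 arrays, 2359 genes lay at or below that percentile.

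The 37 gene lists, the settings and the rule for named genes were fixed before the data were examined. The lists covered transcription regulators and surface proteins of plasma cells and of B cells, B cell receptor signalling, antigen presentation, immunoglobulins, 6 parts of the secretory pathway and its stress response, metabolism, translation, cell cycle, apoptosis, homing, interferon and immediate early genes, and markers of 9 other cell types or stages, plus sex-linked genes. They held 757 symbols, of which 684 were measured. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 37 lists. The named genes were the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes whose arrays did not overlap between groups (leaving out predicted genes, clone names and immunoglobulin segments), up to 3 called members in the main direction and 2 in the opposite direction of each list, or the 2 brightest members of a list without a called member, and 22 genes fixed by name, among them the sort markers Sdc1, Ptprc and Fcer2a. Genes named outside that rule are marked as chosen after their values were seen.

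The procedure was tested on simulated data for the comparison of plasma cells with B cells, drawn from the means and pooled spreads of the 18193 genes with 50 genes changed at each fold. At an 8-fold change 40 of 50 genes were recovered, at a 4-fold change 31 of 50, at a 2-fold change 13 of 50 and at a 1.5-fold change 0 of 50, with 0 calls among 17993 unchanged genes. With 1 of the 37 lists raised by 2-fold, the list test found that list and 0 others. The simulated genes were drawn independently of each other, so this does not check the test for lists with correlated members. In the data the estimated correlation was 0.403 for N-glycosylation and 0.775 for oxidative phosphorylation. Few genes were changed in the simulation while 29.9% were called in the data, so the recovery rates need not carry over.

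Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, leaving out the dimmest 30% of genes, the mean of all probe sets of a gene, leaving out probe sets that can hybridise with more than 1 transcript (suffixes x and s), every probe set on its own, eBayes with trend and robust estimation, array weights, a replicate block, each array left out in turn and, for the lists, an estimated correlation, fry and lists without shared members. Fits with an array left out kept the probe sets chosen on all 6 arrays. The camera calls were also compared with those at an estimated correlation, where 0 of the 37 lists held and 9 had an unadjusted p under 0.05. A fit without X and Y linked genes was chosen after seeing the data.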

Results

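Gene expression was measured in antibody-secreting plasma cells of mouse bone marrow, sorted as B220 negative and CD138 positive, and in naive B cells of the spleen, sorted as B220 positive and CD23 positive. Each group had 3 arrays. The plasma cells were collected 7 days after a boost with the antigen KLH. The comparison asks which transcripts differ between naive B cells of the spleen and antibody-secreting cells of the same lineage in the bone marrow. Tissue, the boost (given for the plasma cells only), bead enrichment and input all differed together with the cell type. Their effects cannot be told apart from those of differentiation. Median intensity over all probe sets was 130 on B cell array 1 and between 86.7 and 95.1 on the other 5 arrays, and the share of probe sets with an intensity under 16 was 13.1% on B cell array 1 and between 20.7% and 22.6% on the others.

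The transcripts of the sort markers followed the gates, which checks the labels and is no finding of its own. Sdc1, which encodes CD138, had an intensity of 12911 ± 282 (SD, n = 3) in plasma cells and 1072 ± 107 in B cells. Fcer2a, which encodes CD23, had 48.1 ± 4.0 in plasma cells and 6032 ± 868 in B cells. Ptprc, whose longer protein forms carry the B220 epitope, had 4236 ± 60.7 in plasma cells and 9453 ± 133 in B cells. The plasma cell arrays resembled each other with Pearson correlations of log2 values between 0.985 and 0.989, taken across probe sets, which are not independent replicates, and B cell arrays 2 and 3 had a correlation of 0.992. B cell array 1 stood apart from them, with correlations of 0.933 and 0.926, and with lower ones of 0.858 to 0.863 with the plasma cell arrays. Lists of other cell types were uneven on that array: the median log2 difference from the mean of arrays 2 and 3 was 1.85 for T and NK cell markers, 1.49 for granulocyte, 1.41 for erythroid, 0.829 for stromal and endothelial, 0.741 for basophil, mast cell and eosinophil and 0.609 for monocyte and macrophage markers. It was 0.102 for megakaryocyte and platelet and −0.156 for dendritic cell markers. Cd3e, a T cell receptor component, was at 1966 on B cell array 1 against 27.2 and 36.5 on arrays 2 and 3, Slc4a1, the anion exchanger of red cells, at 1158 against 18.4 and 37.3, and S100a8, a neutrophil protein, at 4444 against 892 and 644. Xist, the transcript of the inactive X chromosome, was at 8408 on B cell array 1 and at 30.8 and 18.1 on arrays 2 and 3, while the Y-linked Kdm5d was at 3.6 on array 1 and at 1507 and 1576 on arrays 2 and 3. All 3 plasma cell arrays had high Xist, 8339 ± 326, and Kdm5d between 3.0 and 8.8, so the groups were not matched for these sex-linked genes. Without B cell array 1 every plasma cell array differed from every B cell array in them. Sex and cell type cannot be told apart in that fit, and little better with array weights, where that array weighed 0.0938. Cd3e, Slc4a1, S100a8 and Kdm5d were chosen after their values were seen. Of the 4 measured sex-linked genes 0 were called by limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.461). Without B cell array 1 the 5 genes named here for it were called, Xist with adjusted p = 4.43e-05, Kdm5d with 5.3e-05, Slc4a1 with 0.00602, S100a8 with 0.00669 and Cd3e with 0.00902. Over all alternatives their adjusted p reached 0.285, 0.311, 0.997, 0.328 and 0.994.

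**Figure D1:**
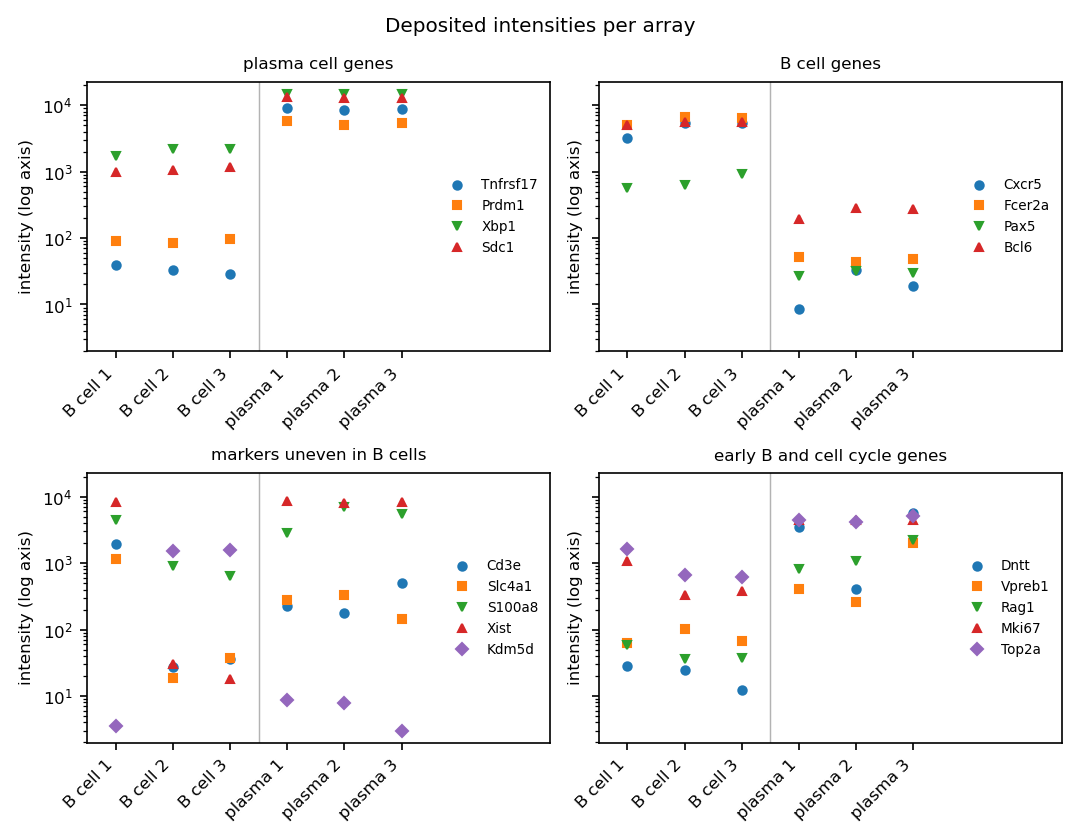
Deposited intensity of selected genes on each of the 6 arrays (log axis, 1 point per gene and array, B cell arrays left of the vertical line and plasma cell arrays right of it). Tnfrsf17 and Prdm1 were higher on every plasma cell array than on any B cell array, Cd3e and Xist were higher on B cell array 1 than on B cell arrays 2 and 3, and Dntt ranged from 413 to 5670 over the plasma cell arrays.

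Plasma cells and B cells differed widely. Of 18193 genes, 3193 were higher and 2246 lower in plasma cells, 1985 of the former and 1233 of the latter by at least 2-fold. Folds are ordered on the scale with 16 added, which compresses those of dim genes. The highest under the rule for named genes was that of Tnfrsf17, the receptor BCMA for the survival factors APRIL and BLyS. It was at 8730 ± 288 (SD, n = 3) in plasma cells and 33.4 ± 5.2 in B cells (log2 fold change 7.47 ± 0.13 SE, adjusted p = 1.71e-05). The others of the first 10 were the paraoxonase Pon3 (7.15), the cilium-associated gene Rsph1 (at least 175-fold higher without the added constant, since it lay within background on all B cell arrays), the granule protein gene Prg2 (7.09) and the costimulatory receptor Cd28 (6.94 ± 0.80). They also included the extracellular matrix gene Reln (6.73), the secretory cell transcription factor Bhlha15 (6.68), the actin-bundling gene Pls1 (6.66), Oosp1 (6.44) and the phosphoglycerate mutase Pgam2 (at least 65.3-fold higher, likewise). The order depends on the constant and on the arrays used. With a pseudocount of 1 the log2 fold changes of Cd28 (8.36) and Pgam2 (8.06) exceeded that of Tnfrsf17 (8.0), and genes within background on the B cell arrays cannot be ranked. Among the B cell arrays Cd28 lay over background on array 1 alone, at 130 against 2.8 and 5.0 on arrays 2 and 3. Without that array its log2 fold change was 7.90, above the 7.55 of Tnfrsf17. The value of 7.90 rests on B cell intensities within background and so depends on the added constant. At the other end stood the follicle-homing chemokine receptor Cxcr5, at 20.02 ± 12.1 in plasma cells and 4683 ± 1254 in B cells (−7.04 ± 0.33, adjusted p = 7.33e-05). With it came the Toll-like receptor Tlr1 (−7.00), Fcer2a (−6.55), the antigen presentation gene H2-Oa (−6.50), the class II transactivator Ciita (−6.43), Ms4a4c (−6.30), the kinase Lrrk2 (−6.19), the complement receptor Cr2 (−6.10), the inhibitory receptor Cd22 (−5.96) and the lymph node homing receptor Ccr7 (−5.72). With a pseudocount of 64 Tlr1 (−6.10) and H2-Oa (−5.82) were lower than Cxcr5 (−5.79). In plasma cells Cxcr5 and Lrrk2 lay over background on 1 array only, so their folds and ranks depend on the constant too. The same limit holds for the folds of Nr4a1, Rgs13 and Csf3r, given below. It also holds for Chac1, Bik and Dntt, which lay over background on 1 B cell array only.

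All 6 arrays of 8694 genes, 47.8% of those tested, lay on separate sides of the group boundary, where chance gives 10%. At an unadjusted p under 0.05 limma counted 7294 genes. The count of lower genes was 3830 without B cell array 1, 1347 without plasma cell array 1 and 1369 without plasma cell array 2. It was 1243 after median centring, and array weights gave 4840 higher and 4654 lower genes. Without B cell array 1 sex went with cell type, and array weights gave that array little weight, so the counts of these fits can include effects of sex. Both fits also remove or weigh down an array that differed widely from B cell arrays 2 and 3. On it 2709 genes were at least 2-fold higher and 818 lower than their mean. Which of these moved the counts was not tested.

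**Figure D2:**
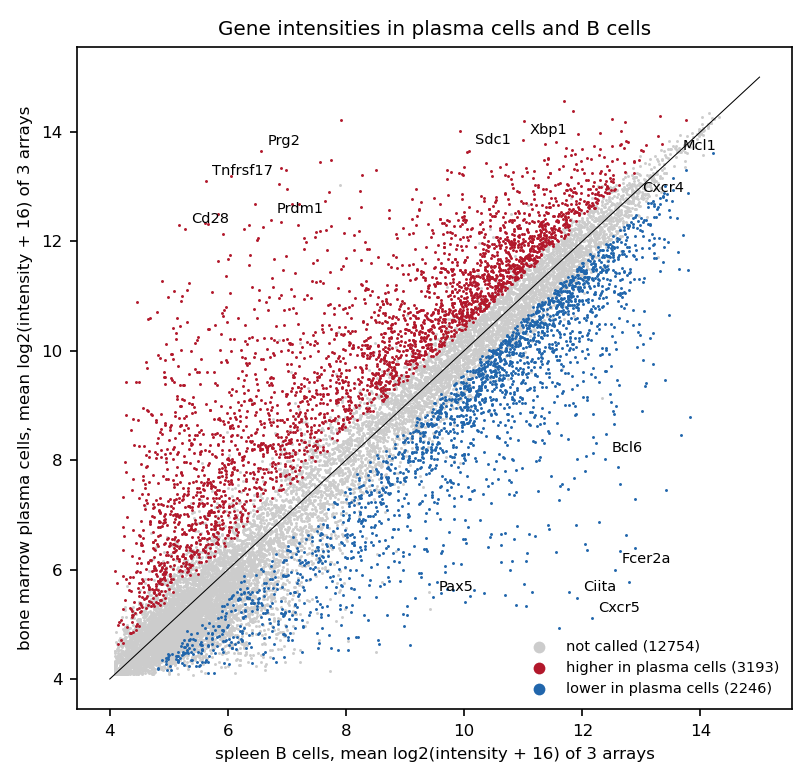
Mean log2(intensity + 16) of the 3 B cell arrays (x axis) against that of the 3 plasma cell arrays (y axis), 1 point per gene, with the line of equality. The 3193 genes called higher in plasma cells are red, the 2246 called lower are blue and the 12754 not called are grey; Mcl1 and Cxcr4 lie near the line.

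Of 12 measured transcription regulators of plasma cells 8 rose and 1 fell (2 fell adjusted over the list alone; camera adjusted p = 0.00021, adjusted p = 0.317 with an estimated correlation). Prdm1, which encodes Blimp-1, the repressor that drives plasma cell differentiation, had 5371 ± 283 (SD, n = 3) in plasma cells and 89.8 ± 6.2 in B cells (log2 fold change 5.67 ± 0.12 SE, adjusted p = 1.71e-05). Xbp1, the regulator of the secretory apparatus, rose by 2.85 ± 0.14, the membrane-bound regulator Creb3l2 by 5.12 ± 0.25 and Irf4, which acts in both stages, by 1.12 ± 0.12. Another probe set of Irf4, dimmer in both groups, rose by 3.525 ± 0.14, so the size of its rise depends on the probe set. Other probe sets of Xbp1 rose by 2.77, 3.31 and 3.81. The plasma cell values of the probe sets used for Xbp1 and Irf4 lie within 2-fold of the highest value of their arrays. Their folds can therefore understate the change. Zbtb20 rose by 1.26 ± 0.17, and all 9 of its probe sets were called higher. Zbtb32 was the member that fell, from 106 ± 1.9 in B cells to 44.0 ± 8.7, a call that was lost when all probe sets of the gene were averaged (adjusted p = 0.117, and from 0.000452 to 0.117 over the alternatives). Among 12 measured plasma cell surface proteins 10 rose and 1 fell (11 rose adjusted over the list alone; camera adjusted p = 9.51e-08, adjusted p = 0.0974 with an estimated correlation). That list holds the sort marker Sdc1. Besides Tnfrsf17 and Cd28 the raised members included the adhesion molecule Epcam (4.77 ± 0.15). The cytokine receptor Lifr fell (−2.86 ± 0.47).

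Of 22 measured B cell transcription regulators 0 rose and 16 fell (1 rose and 18 fell adjusted over the list alone; camera adjusted p = 4.08e-08, adjusted p = 0.184 with an estimated correlation). Pax5, the factor that maintains B cell identity, had 29.3 ± 2.6 in plasma cells and 707 ± 194 in B cells (−3.97 ± 0.21, adjusted p = 0.000102). It lay over background on only 1 plasma cell array, so the size of its fall depends on the added constant. Bcl6, the germinal centre regulator, fell (−4.36 ± 0.18), as did Id3, an inhibitor of E proteins (−4.69 ± 0.59). Bach2 (−2.41 ± 0.48) and Spib (−2.81 ± 0.61) fell too but were uneven over the plasma cell arrays, at 621, 963 and 2360 for Bach2 and 652, 1613 and 3848 for Spib. The call of Bach2 was lost without plasma cell array 2 (adjusted p = 0.0531), and that of Spib without B cell array 2 (0.0583), B cell array 3 (0.0592) or plasma cell array 2 (0.0617). Over all alternatives the adjusted p of Bach2 ranged from 0.00154 to 0.0531 and that of Spib from 0.00326 to 0.0617.

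Genes of B cell receptor signalling fell, 18 of 24 measured, with 1 that rose (camera adjusted p = 9.51e-08, adjusted p = 0.317 with an estimated correlation; the same counts held adjusted over the list alone). Beside Cr2 and Cd22, the scaffold Bank1 fell by 3.21 ± 0.17. The receptor chains, chosen after their values were seen, fell by less, Cd79a with a log2 fold change of −0.57 and Cd79b of −0.45. Both calls were lost after median centring and without any 1 of the 3 plasma cell arrays, B cell array 2 or B cell array 3, with adjusted p between 0.081 and 0.129 without those arrays and up to 0.322 and 0.451 over all alternatives. A pseudocount of 1 also ended the call of Cd79b (0.0522). Of 21 follicular B cell surface genes 16 fell and 0 rose (camera adjusted p = 1.05e-08, adjusted p = 0.184 with an estimated correlation), again with the same counts adjusted over the list alone; that list holds the sort marker Fcer2a. In the MHC class II pathway, which presents antigen to T helper cells, 12 of 18 members fell and 0 rose, also adjusted over the list alone (camera adjusted p = 9.51e-08, adjusted p = 0.0974 with an estimated correlation). Ciita, its master regulator, had 28.9 ± 2.6 in plasma cells and 3905 ± 836 in B cells, and Marchf1, a ubiquitin ligase for class II molecules, fell by 5.57 ± 0.31. Cd74, the invariant chain, chosen after its values were seen, was at 19839 ± 391 in plasma cells and 20303 ± 1751 in B cells and was not called. Both values lie near the upper end of the scale, where the highest values of the arrays were 25764 to 26749, so a difference could be hidden there.

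The measured members of the immunoglobulin list rose. Of its 14 fixed members only 5 were measured, Jchain among them, so most of the list was not tested. All 5 were called higher, also adjusted over the list alone (camera adjusted p = 6.94e-05, adjusted p = 0.0974 with an estimated correlation). The constant region probe sets can share sequence with each other. Ighg3 rose by 4.08 ± 0.13 (16588 ± 1522 against 964 ± 70.1), Igha by 2.88 ± 0.41 (24270 ± 297 against 3681 ± 2187), and Jchain, which joins polymeric antibody, by 2.55 ± 0.20 (21424 ± 529 against 3715 ± 961). Ighm rose by 0.98 ± 0.12, from 10177 ± 925 to 20057 ± 353. The plasma cell values of Ighg3, Igha, Jchain and Ighm lie within 2-fold of the highest value of their arrays, so these folds can understate the change. For Ighm all 11 probe sets were called higher, with log2 fold changes between 0.91 and 6.94. Several were dim and uneven on the B cell arrays. The one with 6.94 was at 1051, 10.9 and 145 there, where the probe set used was at 9112, 10639 and 10778. The 11 are therefore not repeated measures of the same transcript level.

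Of 27 endoplasmic reticulum (ER) chaperones and oxidative folding genes 26 rose and 0 fell (27 rose adjusted over the list alone; camera adjusted p = 3.19e-16, adjusted p = 0.0974 with an estimated correlation). The chaperone-associated gene Sdf2l1 rose by 3.77 ± 0.13 and the peroxiredoxin Prdx4 by 3.58 ± 0.11, to 12684 ± 398 from 1049 ± 30.4. The prolyl isomerase Fkbp11 rose by 5.19 ± 0.17, a call that was lost when probe sets with the suffixes x and s were left out (adjusted p = 0.291, the highest over the alternatives, against a lowest of 1.38e-06). In ER-associated degradation, which removes misfolded proteins, 17 of 19 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.65e-11, adjusted p = 0.184 with an estimated correlation). Derl3 led them with 7957 ± 15.7 against 113 ± 8.1 (log2 fold change 5.95 ± 0.11, adjusted p = 1.71e-05), followed by Edem2 (3.26 ± 0.17). Translocation into the ER and signal peptide processing had 22 of 23 members higher and 0 lower, also adjusted over the list alone (camera adjusted p = 4.67e-13, adjusted p = 0.181 with an estimated correlation), among them Tram2 (3.35 ± 0.12), Spcs2 (2.74 ± 0.13) and Srprb (2.70 ± 0.15). For N-glycosylation 20 of 30 rose and 0 fell (22 rose adjusted over the list alone; camera adjusted p = 2.49e-08, adjusted p = 0.330 with an estimated correlation), with Gmppb (2.78 ± 0.21), Alg2 (2.47 ± 0.11) and Dpagt1 (2.36 ± 0.17) in front. COPII and COPI vesicle transport between ER and Golgi had 36 of 40 members higher and 1 lower (37 and 1 adjusted over the list alone; camera adjusted p = 1.58e-15, adjusted p = 0.267 with an estimated correlation), led by Arfgap3 (4.19 ± 0.29), Sec24d (3.84 ± 0.15) and Kdelr3 (3.02 ± 0.28).

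The stress arm that runs through PERK, ATF4 and CHOP was mixed. Of 15 members 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0046, adjusted p = 0.425 with an estimated correlation). The asparagine synthetase gene Asns (5.94 ± 0.21), the glutathione-degrading enzyme gene Chac1 (5.71 ± 0.27) and Atf5 (3.28 ± 0.47) rose strongly. The genes that give the pathway its name were not called: Eif2ak3 had a log2 fold change of 0.28, Atf4 of 0.31 and Ddit3 of 0.33, all chosen after their values were seen. Eif2ak3 was called higher with the mean of its probe sets (adjusted p = 0.0144) and with array weights (0.0463), with a highest adjusted p of 0.392 over the alternatives. Amino acid uptake and synthesis had 15 of 23 members higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 8.86e-07, adjusted p = 0.0974 with an estimated correlation), with Gpt2 (3.77 ± 0.11) and Slc1a4 (3.71 ± 0.52) beside Asns. Aminoacyl-tRNA synthetases, which charge tRNAs, had 13 of 19 higher and 0 lower (14 higher adjusted over the list alone; camera adjusted p = 1.07e-05, adjusted p = 0.464 with an estimated correlation), led by Yars (2.66 ± 0.36), Nars (1.59 ± 0.11) and Cars (1.53 ± 0.14). Of 27 cytosolic ribosomal protein genes 0 were called by limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.783). Rpl35 was at 0.05 ± 0.15 (19394 ± 259 against 18895 ± 2726) and Rpl4 at −0.01 ± 0.12 (18287 ± 511 against 18416 ± 1690). On every array 16 of the 27 lay within 2-fold of its highest value, where a difference could be hidden. A lack of change is therefore not shown.

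In energy metabolism, 15 of 39 genes of oxidative phosphorylation rose and 0 fell, also adjusted over the list alone (camera adjusted p = 3.44e-06, adjusted p = 0.604 with an estimated correlation), with Ndufa1 (2.23 ± 0.17), Ndufa9 (1.16 ± 0.13) and Ndufb9 (1.14 ± 0.14) changed most. Glycolysis was split, with 6 of 18 members higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.118). The hexokinase Hk2 (2.23 ± 0.14) and the phosphofructokinase Pfkm (2.67 ± 0.17) rose. The glucose transporter Slc2a3 fell (−2.06 ± 0.24), a call that was lost when probe sets with the suffixes x and s were left out (adjusted p = 0.275, and from 0.000154 to 0.275 over the alternatives). Of 24 autophagy genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00248, adjusted p = 0.425 with an estimated correlation). Wipi1, which acts in autophagosome formation, rose by 5.68 ± 0.11, and Gabarapl1 by 2.20 ± 0.33 and Atg13 by 2.00 ± 0.25.

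**Figure D3:**
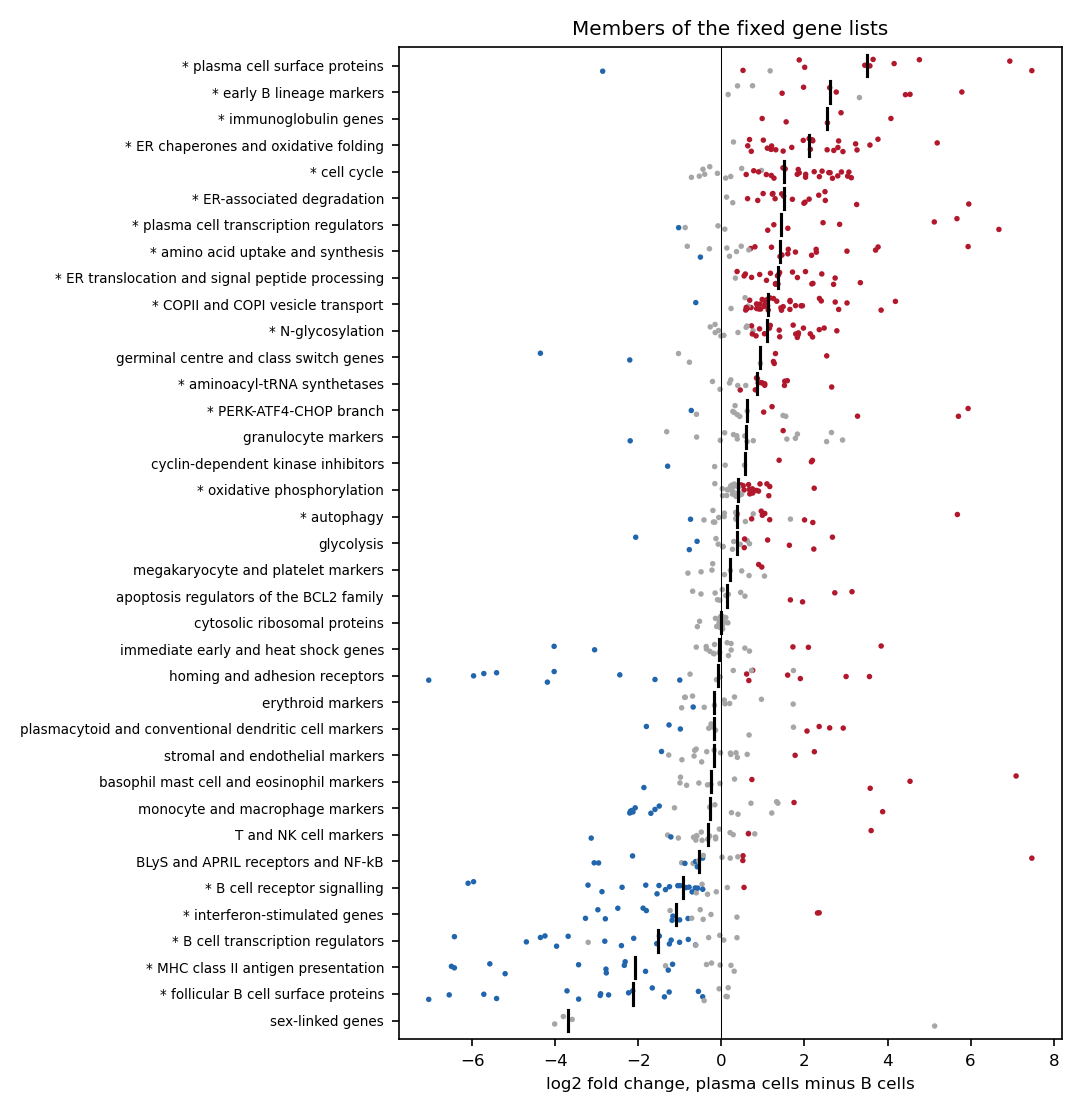
Log2 fold change (plasma cells minus B cells, x axis) of each measured member of the 37 gene lists, 1 point per gene, red if called higher, blue if called lower and grey if not called; the black bar is the median and an asterisk marks lists called by camera at the preset correlation. The ER chaperone list has its median at 2.11 and the follicular B cell list at −2.13.

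Cell cycle genes were higher in the plasma cells. Of 34 measured members 24 rose and 0 fell (26 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.31e-07, adjusted p = 0.256 with an estimated correlation). The proliferation marker Mki67 had 4468 ± 35.2 (SD, n = 3) in plasma cells and 598 ± 415 in B cells (log2 fold change 3.07 ± 0.44 SE, adjusted p = 0.00348), the mitotic kinase Cdk1 rose by 3.13 ± 0.40 and the mitotic ubiquitin conjugase Ube2c by 3.04 ± 0.45. Mki67 was higher on B cell array 1, at 1076, than on arrays 2 and 3, at 332 and 385. The replication genes named next were chosen after their values were seen. Cdc6 rose by 2.67 ± 0.15 (331 ± 47.1 against 38.2 ± 5.7, adjusted p = 0.000135), and Mcm6 by 0.90 ± 0.17 (adjusted p = 0.0115), a call that was lost without plasma cell array 1 (0.0527, the highest over the alternatives, against a lowest of 0.00169). Mcm2, Mcm3, Mcm4, Mcm5 and Mcm7 had log2 fold changes of 0.23, −0.10, −0.40, −0.44 and −0.53 and were not called, and neither was the sliding clamp gene Pcna at 0.10. With array weights Mcm4, Mcm5 and Mcm7 were called lower (adjusted p = 0.022, 0.0198 and 0.0189, against highest values of 0.521, 0.98 and 0.951 over the alternatives). Of 7 cyclin-dependent kinase inhibitors 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.25). Cdkn2c rose by 2.19 ± 0.16 (1701 ± 96.3 against 363 ± 64.9) and Cdkn2d fell (−1.29 ± 0.21), while Cdkn2b was at least 3.1-fold higher, since it lay within background on all B cell arrays.

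Of 14 regulators of apoptosis of the BCL2 family 4 rose and 0 fell (5 rose adjusted over the list alone; camera adjusted p = 0.112, 0.025 with the mean of all probe sets, and from 2.19e-05 with fry to 0.341 over the alternatives). The prosurvival genes Bcl2l1 (2.73 ± 0.12) and Bcl2l2 (1.95 ± 0.21) and the BH3-only gene Bik (3.14 ± 0.31) were among them. Bcl2 (−0.09 ± 0.14) and Mcl1 (−0.04 ± 0.12) were not called, although 1 of the 6 probe sets of Mcl1 was called higher. Among 17 receptors for BLyS and APRIL and NF-kB genes 3 rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.172). Tnfrsf17 rose as given above, while the NF-kB subunit gene Rel (−3.06 ± 0.34), the adaptor Traf5 (−2.96 ± 0.21) and the kinase Map3k14 (−2.14 ± 0.33) fell. Without B cell array 1 this list was called lower (adjusted p = 0.0145), as it was with array weights (0.0333) and without members shared between lists (0.0366), with a highest adjusted p of 0.783 over the alternatives. The other receptors of these ligands changed far less, Tnfrsf13b, which encodes TACI, by 0.52 ± 0.11 and Tnfrsf13c, which encodes the BLyS receptor BAFF-R, by −0.45 ± 0.13. Both calls were lost after median centring and without any 1 of the 3 plasma cell arrays or B cell array 2, and that of Tnfrsf13c also without B cell array 3 (adjusted p between 0.0604 and 0.145 without those arrays, 0.124 and 0.453 after median centring). A pseudocount of 1 also ended the call of Tnfrsf13c (0.0585).

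Homing and adhesion receptors changed in both directions, 7 of 22 higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.462). Cxcr5, Cd22 and Ccr7 fell most. The inflammatory chemokine receptor Cxcr3 rose by 3.56 ± 0.13 (2858 ± 245 against 227 ± 20.2), and Ccr10, a receptor for mucosal chemokines, was at least 9.4-fold higher. Cxcr4, which retains plasma cells in the marrow, had 7050 ± 201 in plasma cells and 7688 ± 947 in B cells (−0.12 ± 0.14, adjusted p = 0.570). Of 9 germinal centre and class switch genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.783, with a median log2 fold change of 0.94 and a mean of −0.12). S1pr2 rose by 2.54 ± 0.16 and the uracil glycosylase Ung by 1.27 ± 0.16, while Bcl6 and Rgs13 (−2.20 ± 0.28) fell.

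Interferon-stimulated genes fell, 10 of 18 measured, and 2 rose (3 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.00243, adjusted p = 0.377 with an estimated correlation). Ifit3 (−3.27 ± 0.27), Ifit2 (−2.97 ± 0.34) and Oas2 (−2.79 ± 0.21) fell, and Bst2 (2.35 ± 0.17) and Zbp1 (2.31 ± 0.13) rose. Among 20 immediate early and heat shock genes, which respond within minutes to handling, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.891, with a median of −0.05 and a mean of 0.02). Nr4a1 (−4.03 ± 0.51) and Egr3 (−3.05 ± 0.19) fell and Fos rose (1.72 ± 0.24). Fosb (3.85 ± 0.86) and Jun (2.09 ± 0.45) rose as well, but Fosb was at 3002, 728 and 6651 on the 3 plasma cell arrays. Both calls were lost without B cell array 2 (adjusted p = 0.0583 and 0.0571) or plasma cell array 1 (adjusted p = 0.0721 and 0.0671, the highest over the alternatives).

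Early B lineage markers were higher in the plasma cell samples, 7 of 11 measured with 0 lower (8 higher adjusted over the list alone; camera adjusted p = 0.000322, adjusted p = 0.377 with an estimated correlation). The terminal transferase Dntt had a log2 fold change of 5.79 ± 0.96, the recombinase Rag1 of 4.43 ± 0.40 and the stem cell factor receptor Kit of 4.54 ± 0.21. Several differed between the plasma cell arrays: Dntt was at 3547, 413 and 5670, Vpreb1, a surrogate light chain gene chosen after its values were seen, at 411, 264 and 2008, and Rag1 at 815, 1075 and 2250. The call of Vpreb1 was lost without any 1 of the 3 B cell arrays or without plasma cell array 1, with adjusted p between 0.0692 and 0.0973. Mki67 was at 4454, 4442 and 4508 on the same plasma cell arrays.

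Of 18 granulocyte markers 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.25), and that list was called higher without B cell array 1 (adjusted p = 0.0211) and with array weights (0.046), with a highest adjusted p of 0.783 over the alternatives. S100a8 was at 2838, 7001 and 5397 on the plasma cell arrays. The receptor Csf3r fell (−2.19 ± 0.31). Of 19 monocyte and macrophage markers 2 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.289); the lysozyme Lyz2 (−2.21 ± 0.29) and Adgre1 (−2.19 ± 0.31) fell, and the mannose receptor Mrc1 (3.88 ± 0.42) and Cd68 (1.75 ± 0.12) rose. Of 13 erythroid markers 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.462). Among 21 T and NK cell markers 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.460): Cd4 was at least 13.4-fold higher (388 ± 73.8 against 17.1 ± 5.8), and Cd2 fell (−3.13 ± 0.20). For 14 dendritic cell markers the counts were 4 and 3, also adjusted over the list alone (camera adjusted p = 0.717, median −0.17 and mean 0.51), with Cox6a2 (2.93 ± 0.30) higher and Pacsin1 (−1.80 ± 0.20) lower. For 11 megakaryocyte and platelet markers they were 2 and 0 (camera adjusted p = 0.461) and for 17 stromal and endothelial markers 2 and 1 (camera adjusted p = 0.883), both also adjusted over the list alone.

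Of 13 basophil, mast cell and eosinophil markers 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.559, median −0.25 and mean 0.80). Prg2, which encodes the major basic protein of eosinophil granules, had 12882 ± 652 (SD, n = 3) in plasma cells and 83.2 ± 39.3 in B cells (log2 fold change 7.09 ± 0.29 SE, adjusted p = 4.84e-05), and the related gene Prg3 was at least 11.8-fold higher. Other eosinophil genes, chosen after their values were seen, were not: Epx had 10.03 ± 7.5 in plasma cells, Siglecf 5.2 ± 0.7 and the eotaxin receptor Ccr3 11.9 ± 3.5, none of them called. Siglecf was called lower without B cell array 3 (adjusted p = 0.0357) and with array weights (0.0189), and Epx with array weights (0.0329), against highest values of 0.242 and 0.616 over the alternatives.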

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

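The tests of explanations in this part were chosen only after the patterns had been seen, while the counts of other splits were planned before the data were examined.

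Probe sets without a usable gene name carried signal that the gene comparisons do not use. Among 9160 probe sets without a symbol here, 512 were higher in plasma cells than in B cells and 1459 lower (limma, adjusted over all probe sets other than controls), with log2 fold changes from −6.68 to 6.88. Among 932 probe sets with several symbols, 152 were higher and 80 lower, with log2 fold changes from −5.04 to 7.23.

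B cell array 1 stood apart from the other B cell arrays. On it 2709 genes were at least 2-fold higher and 818 lower than the mean of arrays 2 and 3, where arrays 2 and 3 differed by that much in 69 and 127 genes. Raised background is argued against as the whole source, since the bacterial controls rose there by a mean of 0.108 (log2) while other probe sets of their level rose by 0.653. Their upper end did rise, with a 95th percentile of 40.6 against 23.0 and 25.2 and a maximum of 115 against 33.2 and 34.7. The spiked control bioB had a mean of 4368 against 1938 and 1950 and bioC of 7170 against 3545 and 3552, so a difference in labelling or hybridisation of this array stays open. Genes of the sex chromosomes are argued against as the whole source by their number alone, since 17567 of the 18193 genes remained without them. The mean correlation with arrays 2 and 3 was then 0.947, and 0.946 with all genes, against 0.994 between those, a result that so few genes could hardly have changed. Transcripts of other cell types remain a candidate explanation: the 126 members of 8 lists of other cell types rose by a median of 0.735, above the 95th percentile of 10000 random gene sets matched on level (0.399, median 0.248). Hbb-b2 and S100a8 were chosen after their values were seen: Hbb-b2 was at 8450 there against 446 and 439, and S100a8 at 4444 against 892 and 644. Another globin gene, Hba-a2, did not differ in this way, at 7999 against 7969 and 8148. The sort on B220 and CD23 would remove such cells, 84 of the 126 members lay over background on B cell arrays 2 and 3 as well, 6 are held by another list, and 2 of the lists did not follow, with a median of −0.156 for dendritic cell and 0.102 for megakaryocyte and platelet markers. Xist, at 8408 against 30.8 and 18.1, and Kdm5d, at 3.6 against 1507 and 1576, the latter chosen after its values were seen, show that the material of this array differed in sex from that of arrays 2 and 3. Whether an array holds 1 animal or several is not given. Whether that difference or another preparation accounts for the genes outside the sex chromosomes stays open and was not tested.

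Early B lineage transcripts were uneven across the plasma cell arrays. Their 11 measured markers had a median log2 range of 1.67 over the 3 arrays, above the 95th percentile of 10000 random sets matched on level (0.293, median 0.188), which describes the pattern and tests no explanation of it. For early B lineage cells in the sort, 9 measured transcripts of that lineage from outside the list (Akap12, Arpp21, Bcl7a, Blnk, Cecr2, Cnn3, Ebf1, Lef1 and Myb), chosen after the pattern was seen, were compared between plasma cell arrays 3 and 2. Their median difference was 0.871, above the 95th percentile of 10000 random sets matched on level (0.141, median 0.0302), with 7 of the 9 higher on array 3, and this is consistent with more of such cells on array 3 than on array 2. It does not carry over to array 1: between arrays 1 and 2 the same transcripts had a median difference of −0.142 (random sets 0.0182, 95th percentile 0.097), with 6 of the 9 lower on array 1, where Dntt was higher. The called markers rose from array 2 to array 1 by a median part of 0.504 of their rise to array 3. The quartiles were 0.0611 and 1.16, too wide a spread to say what the 9 should show. Igll1 entered with a part of 42, since it hardly differed between the arrays, and the other markers lay between −0.221 (Rag1) and 1.72 (Kit). The difference between arrays 1 and 2 therefore stays open. On the medians alone, the bound of 0.5 set first, it would have argued against such cells there. The median reaches that bound only with Igll1 counted, so nothing is drawn from it. Blnk, with the highest intensity of them on these arrays, did not follow, at 7626 on array 2 and 7474 on array 3, while Myb was at 3933 and 5403 and Ebf1 at 2084 and 3824. On the B cell arrays Blnk was at 7194, 8747 and 8947, and so high a level in both groups could hide a small rise. All 9 lay over background on the B cell arrays as well, and 2 of them are held by another list. Cnn3 (7734, 8017 and 8278) and Ebf1 (7329, 7094 and 7011) were higher on every B cell array than on any plasma cell array. Only Myb was lower on every B cell array, at 2307, 2491 and 2718, and the rest overlapped. The rise of these transcripts on array 3 therefore does not tell early B lineage cells from other cells of the B lineage. Dntt was at 3547, 413 and 5670 on these arrays. Sorting for cells without B220 would remove stages that carry B220, but not stages without it. Pax5 stayed at 29.3 ± 2.6 against 707 ± 194 in B cells, 8 of the 11 markers lay over background on all B cell arrays too, and 2 are held by another list. The 16 called follicular genes, used to weigh mature B cells, differed between plasma cell arrays 3 and 1 by a median of −0.927% of their B cell level. Spib differed by 28.3%. The 16 were taken because they were called lower, which favours genes that are low and even on the plasma cell arrays. Of the 21 measured, 5 were left out by that choice. Follicular B cells are therefore argued against only for these 16 genes, and other mature B cells were not tested. The same early cells are also argued against as the source of Igll1, chosen like Vpreb1 after its values were seen, whose log2 range over the arrays was 0.0639 against 2.85 for Vpreb1. Differences between the plasma cells themselves stay open.

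Cell cycle genes were higher in plasma cells, and cycling cells of another type in the sort were weighed as the source. The 24 called genes differed by a median of 0.192 between plasma cell arrays 3 and 2, where 7 early B lineage markers differed by 1.67, and by 0.0254 between arrays 2 and 1, where 13 granulocyte markers differed by 1.17. The upper quartiles of the cell cycle genes, 0.325 and 0.115, lay below the lower quartiles of these markers, 0.697 and 0.680. The cell cycle genes and the early B lineage markers were both kept because limma called them, which favours genes even over the plasma cell arrays. For these 24 genes the quartiles argue against early B lineage cells as the whole source. The granulocyte markers were taken only for lying over background on the plasma cell arrays. With genes chosen by such unlike rules, the comparison does not decide on granulocytic cells. Erythroid cells stay open: between arrays 2 and 3 the cell cycle genes differed by −0.192 and 4 erythroid markers by a median of 0.451, but only 2 of the 4 were higher on array 2, and Hba-a2 was at 4803 and 5557. Of the markers 8 of the 13 and 3 of the 4 lay over background on all B cell arrays as well. Division among the sorted CD138 positive cells themselves stays open too, and other cycling cell types were not tested.

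Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 5439 called genes, the highest of the other splits 0, and 1 of the 10 gave as many. With a 2-fold change the numbers were 3218, 0 and 1. For lists the real split called 20, the highest of the others 24, and 5 of the 10 splits called as many; each of the other splits puts 2 arrays of a cell type on a side and so still carries part of the difference between the cell types.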

How the results depend on the processing

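The alternatives were fixed before the data were examined, except the fit without X and Y linked genes, which was chosen after seeing the data and gave 3086 higher and 2188 lower genes. Over the gene-level alternatives, the genes changed by at least 2-fold ranged from 1674 (pseudocount 64) to 2265 (median centring) higher and from 998 (pseudocount 64) to 1613 (array weights) lower, against 1985 and 1233. Array weights moved the counts of called genes to 4840 higher and 4654 lower, with weights from 0.0938 for B cell array 1 to 3.9 for B cell array 2. With B cell array 1 left out sex went with cell type, and with so low a weight nearly so. Median centring gave 1243 lower genes; it shifted the median log2 fold change of all genes by 0.117, and higher genes made up 67.6% of the calls against 58.7%. With an array left out, the lower genes ranged from 1347 (without plasma cell array 1) to 3830 (without B cell array 1), and 2111 higher and 1236 lower genes kept their call in all 6 such fits. Except for median centring, where the shift is part of the alternative, the cause was not tested.

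With an estimated correlation camera called 0 lists higher and 0 lower (adjusted p from 0.0974 to 0.970, 9 lists at an unadjusted p under 0.05). Under the other alternatives all 20 called lists kept their call and direction. Fry, which does not compare a list with other genes, called 7 further lists. Whether the replicate numbers pair the samples cannot be told. The deviations of same-numbered arrays from their group means had correlations across genes of 0.0484, 0.00469 and 0.0458, and those of other pairs lay between −0.0441 and 0.0316. All are small, and with 3 arrays per group the deviations depend on each other. With the replicate number as a block 2457 genes were higher and 1664 lower, 1910 and 1180 by at least 2-fold, with 15 lists higher and 5 lower. In that fit 12 of the single genes followed below lost their call, among them Cd79a (adjusted p = 0.0677), Cd79b (0.11), Tnfrsf13b (0.0783), Tnfrsf13c (0.123) and Vpreb1 (0.0612).

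Of 198 single genes followed, which include all genes named here, 155 kept their side of the threshold and their direction under every alternative that tested them. The T cell gene Cd247 changed direction, with a log2 fold change of 0.65 and of −0.0295 (adjusted p = 0.94) with the mean of its probe sets; its adjusted p ranged from 0.000831 to 0.94 over the alternatives. Arpp21 did so too, from −0.15 and not called to 1.14 and called higher with the mean of its probe sets (adjusted p = 0.00773, against a highest of 0.956 over the alternatives). Of the 4 probe sets of Cd247, 1 was called higher and 1 lower, so its direction depends on the probe sets used. For Arpp21 the cause was not tested. Among all called genes, 118 had a probe set called the opposite way. Signal over background limits the dimmest genes, of which 2359 lay within that of the bacterial controls on all 6 arrays.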

Other observations

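The genes in this part were chosen after their values were seen. They were called as single genes by limma, adjusted over all genes, except where stated, and none of their families was tested as a list. Tlr3, a sensor of double-stranded RNA, fell (log2 fold change −4.58 ± 0.28 SE), and so did the cytokine receptors Il4ra (−5.07 ± 0.35), Il21r (−4.17 ± 0.23), Il10ra (−3.81 ± 0.24) and Il27ra (−3.39 ± 0.17). The lymphotoxin gene Lta fell (−5.71 ± 0.29), to 25.6 from 2127, as did Tnf (−4.60 ± 0.67). Tlr2, a receptor for bacterial lipoproteins, was higher in plasma cells (1.20 ± 0.20, adjusted p = 0.00684).

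The metallothioneins Mt1 and Mt2 rose by 6.23 ± 0.21 and 6.23 ± 0.23. The voltage-gated calcium channel genes Cacna1s, Cacna1h and Cacna1d rose by 5.66 ± 0.29, 5.53 ± 0.34 and 3.41 ± 0.17, and the potassium channel genes Kcnmb4 (5.22 ± 0.15) and Kcnn4 (3.48 ± 0.13) rose as well. Tmem176a (6.31 ± 0.19) and Tmem176b (5.90 ± 0.24) reached mean intensities of 10060.4 and 11209.9, and the selenoprotein gene Selenom rose by 5.81 ± 0.14.

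In 3 genes with more than 1000 units on every plasma cell array, the highest plasma cell array was at least 2.5 times above the next: Cdipt (18867 on plasma cell array 1, 4427 and 4204 on the others), Aldoa (19028 on array 2, 5800 and 5267 on the others) and Usp4 (12963 on array 3, 2526 and 2284 on the others). A different array stood out in each. Other probe sets of these genes did not follow. The second probe set of Cdipt was at 2051, 1991.8 and 1901.5 on the plasma cell arrays, another of Aldoa at 6398, 6429 and 6077, and that of Usp4 at 540, 570 and 639. None of the 3 genes was called, and without probe sets of the suffixes x and s Cdipt was called higher (0.667, adjusted p = 0.0109, with a highest of 0.534 over the alternatives).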
